A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 78 samples.

How the data were processed

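Steady RNA levels were measured by RNA-seq in 72 samples from 5 strains of Synechococcus elongatus, and RNA polymerase positions by ChIP-seq in 6 libraries of 1 strain. The RNA values are signal values that the authors normalised before deposition: per the file headers they are median-normalised RNA levels, on a linear scale, and what each library was divided by is not stated. The deposited ChIP-seq values used here are positions of the polymerase signal in base pairs, whose unit is other than a count or a signal, per the file headers. The authors name Bowtie as an alignment tool; its version, the genome build and the way reads were counted are not given in the sources used here. The table holds 336 transcripts whose start site was placed by ChIP-seq, and how these were chosen is not stated. Levels ran up to 262.565, with a median of 0.144 over all values, and library sums from 106 to 896. Counts and read depth cannot be recovered from these values, so no counting interval is given.

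Columns were matched to samples by strain, replicate and time as the labels give them, which used 68 columns; 6 wild-type columns match no listed sample and were not used here. Of the 68, 3 columns combine several samples of 1 biological replicate in a manner that is not stated, and were taken as given. Levels were analysed as log2 of the level plus a pseudocount of 0.1. The planned pseudocount for values of this kind was 1; 0.1 was taken instead, before any test, because the median level is far below 1, and 1 was kept as an alternative. R 4.3.3 with limma 3.58.1 was used for all model fits, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 for tables, Fisher's exact tests and figures.

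The 4 strains of the OX-D53E background were fitted together in limma with a mean for each of 28 combinations of strain and time, over 56 libraries, which leaves 28 residual degrees of freedom. The contrasts, the gene lists and the other settings called planned here were fixed before the data were examined. The planned contrasts were the response in OX-D53E (mean of 6, 9 and 12 h minus 0 h), the difference of this response in each deletion strain, and the difference of the mean level over the 7 times. Level differences at 2 and 3 h (early) and at 6, 9 and 12 h (late), and the direct comparison of the rpoD6 and rpoD5 deletions, were added after the 0 h libraries were seen to differ between strains. In the sigF2 deletion strain, cosine and sine terms with a period of 24 h were fitted to 12 values, with 9 residual degrees of freedom, and tested together by limma's F-test. P-values were adjusted by the Benjamini-Hochberg method over the 336 transcripts, with a threshold of 0.05. The fits take libraries as independent, with a random term for the replicate series as another setting. Standard errors use the moderated variance of limma, and SDs are between the 2 replicates.

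The planned gene lists analysed here, set by product name, were clock and output, sigma factors, dark carbon catabolism and respiration, ATP synthase, carbon fixation, photosystem II, tetrapyrrole synthesis, transcription regulators, the NDH complex, cytochrome b6f, ribosomal proteins, tRNA synthetases, chaperones, pili and nitrogen assimilation. Lists for glycogen synthesis, photosystem I, the phycobilisome, the RNA polymerase core, and chromosome and cell division were also planned but were not analysed here. Hydrogenase, cyclic di-GMP signalling and redox protection were added after the product names were read. Lists with at least 3 members were tested by limma's camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. The clock genes kaiA, kaiB and kaiC and the output genes rpaA, rpaB and sasA were not analysed here. The text names the deleted genes, members of the clock, sigma factor and dark catabolism lists, a few members of other lists, and among the 8 largest differences in each direction those with a mean level at or above the median of 0.186 and with both replicates in 1 direction. A planned test of rhythm in the ChIP-seq signal was not run, because the values used here are positions.

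The other settings planned were pseudocounts of 1 and 10, a filter at the lower quartile of mean level, quantile normalization, limma's trend and robust settings, a replicate block, fits of only the strains compared, 12 h alone or a baseline of 0 and 0.5 h, periods of 22 and 26 h, and leaving out each replicate. A pseudocount of 0.01, leaving out the 4 libraries with over 10% of transcripts at 0, array weights, centring each library on its median, leaving out the 0.5 h library of OX-D53E replicate 2 and testing the sigma factor list without the factor deleted in the strain were added after the data were seen. The pipeline was tested on simulated data with 60 of 336 transcripts changed. It found 96.7% of late differences of log2 size 1 and 100% of size 2, with 3 unchanged transcripts called. It found 96.7% of rhythms of amplitude 0.5, with 4 unchanged transcripts called. The simulated noise was independent between libraries, without libraries rich in zeros, deviation shared within a replicate series or shifts in scale. These shares may therefore not hold for the real libraries.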

Results

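The series holds 78 samples of the cyanobacterium Synechococcus elongatus, of which 6 are ChIP-seq libraries and 72 are RNA-seq samples. The ChIP-seq libraries come from cells whose RNA polymerase carries a FLAG tag and was held at promoters by rifampicin, with 1 library at each of 6 times from 24 to 44 h in constant light. RNA-seq covers 5 strains. A strain without sigF2 was followed from 24 to 44 h in constant light, with 14 samples. The other 4 strains share the OX-D53E background, in which the clock genes kaiBC and the native rpaA are deleted and RpaA(D53E), an altered form of the clock output regulator RpaA, is expressed from an IPTG-inducible promoter. OX-D53E itself has 14 samples, and its derivatives without rpoD2, rpoD6 and rpoD5 have 16, 14 and 14. These 4 strains were sampled at 0, 0.5, 2, 3, 6, 9 and 12 h after release from darkness into light, with 100 µM IPTG added after 0 h. Every strain has 2 biological replicates per time. The table of RNA levels lists 336 transcripts in 68 columns that match the RNA-seq samples, in the median-normalised unit of the file, and 137 of the 336 products are named hypothetical protein. The median level per library ran from 0.0118 to 0.25. Read depth per library is unknown, so the number of transcripts listed at 0 served as a guide. It was 158 of 336 in OX-D53E replicate 2 at 0.5 h, 121 in the rpoD6 deletion strain replicate 2 at 0.5 h, 79 in the rpoD2 deletion strain replicate 1 at 12 h and 59 in the rpoD2 deletion strain replicate 2 at 0.5 h, against at most 24 in the others.

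The ChIP-seq table places the polymerase signal near the start codon of each of the 336 genes in each of the 6 libraries. The placement repeated closely over the day. The range of positions over the 6 times had a median of 18 bp, with quartiles of 5 and 61.25 bp and a maximum of 350 bp. It was at most 10 bp for 135 genes (40.2%) and over 100 bp for 45. The mean position lay a median of 64.5 bp upstream of the start codon and lay downstream of it for 14 genes. For the sigma factor genes Synpcc7942_1557, Synpcc7942_1784, Synpcc7942_1746 and Synpcc7942_1849 the mean distance upstream was 146, 71, 127 and 122 bp, and the range over the 6 libraries was 7, 23, 58 and 214 bp. The genome build behind the positions is not given in the sources used here. The strength of the signal was not analysed here.

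Sigma factors, the subunits that direct RNA polymerase to promoters, are the genes deleted in these strains, and 7 of the 336 transcripts are annotated as sigma factors. The file does not pair the symbols of the deleted genes with its tags. In each deletion strain, 1 sigma factor transcript was close to 0 in every library. Synpcc7942_1746, annotated as group 2 factor SigB, had a median level of 0.000235 over 14 libraries of the rpoD2 deletion strain and a highest level of 0.0293, against a lowest level of 0.505 in OX-D53E. Synpcc7942_1557, annotated as principal factor SigA, did not exceed 0.0141 in the rpoD6 deletion strain, against a median of 1.89 in OX-D53E. Synpcc7942_1849, annotated as SigC, did not exceed 0.00887 in the rpoD5 deletion strain, against a median of 0.579 in OX-D53E. Synpcc7942_1784, annotated as SigF, did not exceed 0.00431 in the 12 libraries of the sigF2 deletion strain, against a median of 1.24 in OX-D53E.

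**Figure D1:**
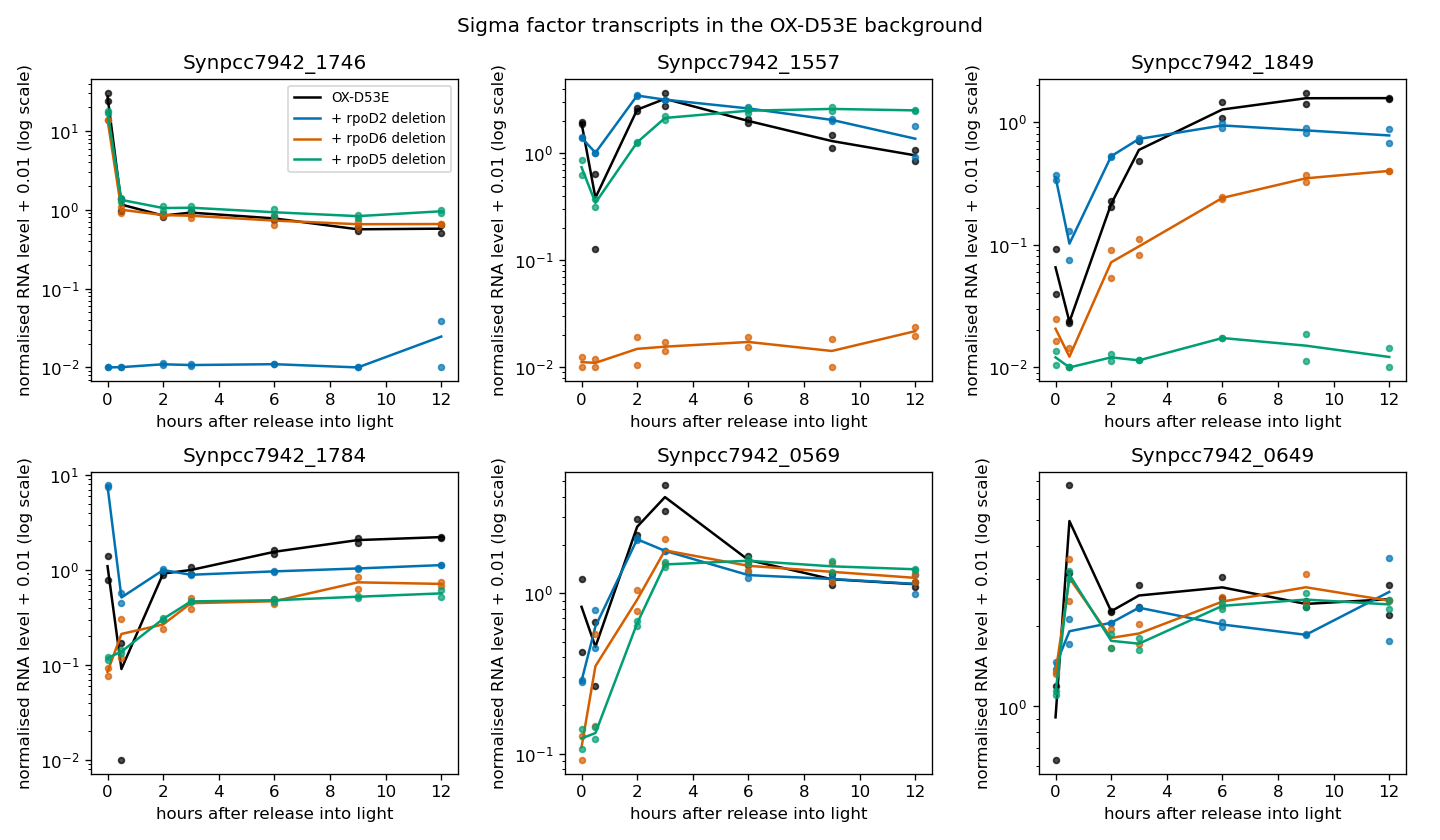
Normalised RNA level plus 0.01 on a log axis against hours after release into light for 6 sigma factor transcripts in the 4 strains of the OX-D53E background; points are libraries and lines join the means of 2 replicates. Synpcc7942_1746 lies near 0 in the rpoD2 deletion strain, Synpcc7942_1557 in the rpoD6 deletion strain and Synpcc7942_1849 in the rpoD5 deletion strain, and Synpcc7942_1849 in the rpoD6 deletion strain stays below OX-D53E, at a mean of 0.318 over 6, 9 and 12 h against 1.44.

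The first comparison asked how transcripts of OX-D53E changed after release into light with induction of RpaA(D53E), from 0 h to the mean of 6, 9 and 12 h. Sugar catabolism and respiration transcripts rose together. Of the 8 listed members of the group fixed for dark carbon catabolism and respiration, 7 rose and 1 fell. Synpcc7942_0245, a glyceraldehyde-3-phosphate dehydrogenase of glycolysis, went from 0.0649 ± 0.0145 to 1.72 ± 0.000576 (SD, n = 2), a log2 change of 3.45 ± 0.16 (SE; limma, adjusted p = 1.86e-19). Synpcc7942_2335, a fructose-1,6-bisphosphatase, rose by 3.65 ± 0.19. Synpcc7942_0244, the phosphorylase that releases glucose units from glycogen, rose by 2.72 ± 0.14, and Synpcc7942_0039, the 6-phosphogluconate dehydrogenase of the oxidative pentose phosphate pathway, by 2.62 ± 0.20. Synpcc7942_2297 (transaldolase) rose by 2.90 ± 0.16, Synpcc7942_2602 (cytochrome c oxidase subunit II) by 2.66 ± 0.20 and Synpcc7942_0639 (phosphopyruvate hydratase, the enolase step) by 0.71 ± 0.25. Synpcc7942_0086, an isoamylase that debranches glycogen, fell by 1.91 ± 0.24. Adjusted over the list alone, the counts were also 7 and 1. The group stood above the other transcripts in limma's camera test (adjusted p = 0.00428 with the preset correlation, adjusted p = 0.0266 with an estimated correlation).

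Sigma factor transcripts moved in both directions in OX-D53E. Synpcc7942_1849 rose from 0.0552 ± 0.0368 to 1.44 ± 0.17 (log2 change 3.32 ± 0.13; limma, adjusted p = 2.01e-20). Synpcc7942_0649 rose by 1.47 ± 0.21, Synpcc7942_1784 by 0.81 ± 0.21 and Synpcc7942_0569 by 0.76 ± 0.28. Synpcc7942_1746 went from 27.4 ± 4.53 to 0.630 ± 0.0262 (log2 change -5.24 ± 0.12), and Synpcc7942_0672 fell by 2.18 ± 0.19. Synpcc7942_1557 was at 1.91 ± 0.0675 at 0 h and 1.41 ± 0.0961 later (log2 difference -0.48 ± 0.23, adjusted p = 0.0745). The counts were 4 higher and 2 lower, and 4 and 3 adjusted over the list alone. Centring each library on its median left 2 higher and 3 lower, with the calls of Synpcc7942_0569 and Synpcc7942_1784 ended. The limma camera test of the list gave adjusted p = 0.870.

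Among the largest changes outside these groups, Synpcc7942_1612, the alpha subunit of a pyridine nucleotide transhydrogenase, which moves reducing equivalents between NADH and NADPH, went from 0.00367 ± 0.00519 to 2.98 ± 0.139. The hypothetical proteins Synpcc7942_2336, Synpcc7942_0304, Synpcc7942_2185 and Synpcc7942_2267 rose by 4.87, 4.08, 3.78 and 3.62 on the log2 scale. The largest falls were those of Synpcc7942_2352, a protein named as sigma 54 modulation and ribosomal, from 123 ± 65.5 to 1.39 ± 0.0356 (log2 change -6.31 ± 0.31), and the hypothetical protein Synpcc7942_0905, from 186 ± 108 to 2.28 ± 0.208. A pair of antioxidant enzymes fell as well, Synpcc7942_2309 (thioredoxin peroxidase) by 4.38 ± 0.19 and Synpcc7942_0623 (thioredoxin reductase) by 3.63 ± 0.20. Of 4 ATP synthase subunits, Synpcc7942_0331, Synpcc7942_0332 and Synpcc7942_0336 rose by 2.27, 2.41 and 2.32 and Synpcc7942_2315 was at 0.0014 ± 0.18 (3 past the threshold over all transcripts and over the list alone; limma camera, adjusted p = 0.329). With centred libraries, 1 subunit was lower. Of 3 carbon fixation transcripts 1 rose and 2 fell (limma camera, adjusted p = 0.657). None of the 3 photosystem II transcripts passed.

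Of the 336 transcripts, 190 passed Benjamini-Hochberg adjusted 0.05 in limma, 121 higher and 69 lower, and 254 differed from 0 h at some later time in the F-test. Against 0 h, 141 differed at 0.5 h, of which 110 were lower; without replicate 2 at 0.5 h, which has 158 transcripts at 0, the counts were 102 and 76. Later, 140 differed at 2 h, 178 at 3 h, 172 at 6 h, 174 at 9 h and 177 at 12 h. The median log2 change of all 336 transcripts was 0.21, and the balance of directions depended on scaling: quantile normalization gave 83 higher and 102 lower, and centred libraries 74 higher and 127 lower. No uninduced culture was compared here, so light and induction act together in these changes.

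The rpoD2 deletion comparison asked whether the time course depends on rpoD2. The largest differences at 2 and 3 h and at 6 to 12 h were those of Synpcc7942_1745, a hypothetical protein whose tag number adjoins that of Synpcc7942_1746. It stood at 12.8 ± 1.08 over 6, 9 and 12 h against 0.0559 ± 0.0145 in OX-D53E (log2 difference 6.40 ± 0.14; limma, adjusted p = 8.69e-29), and at 13.9 ± 0.0604 over 2 and 3 h against 0.0924 ± 0.0217. At 2 and 3 h, 5 of the 8 dark carbon catabolism transcripts were higher than in OX-D53E and none was lower, with Synpcc7942_2335 at 0.74 ± 0.16 and Synpcc7942_0039 at 0.71 ± 0.17 (5 over the list alone as well). At 6 to 12 h, 1 member, Synpcc7942_0639, was higher (0.56 ± 0.17) and 3 were lower, Synpcc7942_2602, Synpcc7942_0039 and Synpcc7942_0245, by -0.71, -0.40 and -0.32. The list did not pass limma camera at either time (adjusted p = 0.119 early and adjusted p = 0.383 late). With quantile normalization the early members were 2 higher and 1 lower.

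Synpcc7942_1849 followed the same course, higher than in OX-D53E at 2 and 3 h (0.613 ± 0.00933 against 0.391 ± 0.0858, log2 difference 0.65 ± 0.12) and lower at 6 to 12 h (0.841 ± 0.0416 against 1.44 ± 0.17, -0.71 ± 0.09). Synpcc7942_1784 was lower late by -0.83 ± 0.15 and Synpcc7942_1557 higher by 0.48 ± 0.16. The thioredoxin peroxidase Synpcc7942_2309 was higher both early (1.25 ± 0.17) and late (0.99 ± 0.14). So were Synpcc7942_1426 (ribulose bisphosphate carboxylase), at 1.08 ± 0.27 and 0.81 ± 0.22, and Synpcc7942_1424 (carbon dioxide concentration), at 1.02 ± 0.29 and 0.73 ± 0.24; the early call of Synpcc7942_1426 was lost with quantile normalization. Synpcc7942_1414 (an ATPase) and the hypothetical protein Synpcc7942_0905 were lower at both, by -1.24 and -2.96 early and -1.22 and -1.46 late. Synpcc7942_0466 (cellulose synthase) was lower early by -1.14 ± 0.16. By the functional categories of the file, a comparison added after the data were seen, 5 of 11 cell wall and membrane transcripts were lower early (45.5% against 6.77% of the others; Fisher's exact test, adjusted p = 0.0168). The larger categories were tested in both directions in every comparison, with adjustment only within each comparison. The search over all comparisons was not adjusted for, and no other scaling is given for this result.

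At 0 h, before induction, the rpoD2 deletion strain already differed in 178 transcripts, 142 higher and 36 lower, with a median log2 difference of 0.43 over all transcripts. The balance depended on scaling, with 74 higher and 71 lower under quantile normalization (110 of the 178 still called) and 88 and 96 with centred libraries (124 still called). The hypothetical protein Synpcc7942_0834 stood at 69.3 ± 1.89 against 0.236 ± 0.124 in OX-D53E, Synpcc7942_1784 at 7.62 ± 0.27 against 1.09 ± 0.438, and Synpcc7942_1838, a subunit of the dark-operative protochlorophyllide reductase, at 2.39 ± 0.0518 against 0.124 ± 0.0538. The response from 0 h to 6 to 12 h differed from that of OX-D53E by -9.15 ± 0.33 for Synpcc7942_0834, -3.58 ± 0.30 for Synpcc7942_1784, -4.24 ± 0.17 for Synpcc7942_1838 and -2.24 ± 0.19 for Synpcc7942_1849. It differed by 3.49 ± 0.33 for Synpcc7942_1447 (carbonate dehydratase), 2.60 ± 0.31 for Synpcc7942_1214 (glutathione peroxidase) and 2.56 ± 0.27 for the sigma factor Synpcc7942_0672.

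In all, 181 of 336 responses differed (34 higher, 147 lower; limma, adjusted 0.05), 143 mean levels over the 7 times differed (108 higher, 35 lower), 74 levels differed at 2 and 3 h (47 higher, 27 lower) and 88 at 6 to 12 h (31 higher, 57 lower). The median response difference of all transcripts was -0.53 on the log2 scale. Under quantile normalization the counts of higher and lower were 68 and 68, 67 and 58, 32 and 35, and 41 and 40, and with centred libraries 98 and 78, 66 and 71, 40 and 19, and 42 and 40. The early count ranged most: 35 with pseudocount 0.01, 43 with only these strains fitted, 39 and 44 without replicate 1 or 2 of the deletion strain, 124 without the 4 libraries rich in zeros and 154 with array weights; the late count was 44 with pseudocount 0.01 and 153 without those 4 libraries. The rpoD2 deletion strain was sequenced in a different season from OX-D53E, so season and deletion cannot be told apart; at 2 and 3 h the replicates of the deletion strain differed with an SD of 0.0568 log2 over transcripts, against 0.278 and 0.387 in OX-D53E.

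The rpoD6 deletion comparison asked the same of rpoD6, with both strains sequenced in the same season. Here the sugar catabolism transcripts were lower. At 6 to 12 h, 7 of the 8 dark carbon catabolism members were lower than in OX-D53E and none was higher (7 lower and 1 higher over the list alone). Synpcc7942_0245 stood at 0.564 ± 0.0101 against 1.72 ± 0.000576 (log2 difference -1.46 ± 0.11; limma, adjusted p = 3.68e-13), Synpcc7942_0039 differed by -1.31 ± 0.14, Synpcc7942_2335 by -1.29 ± 0.13 and Synpcc7942_0244 by -0.98 ± 0.10. At 2 and 3 h, 6 of the 8 were lower (6 lower and 1 higher over the list alone). The list stood below other transcripts in camera at both times (adjusted p = 0.000641 early and adjusted p = 0.00582 late; adjusted p = 0.0125 and adjusted p = 0.0435 with an estimated correlation). Quantile normalization kept 5 members lower and 1 higher at both times, with the late limma camera result at adjusted p = 0.0725, and centred libraries kept 6 lower and 1 higher.

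Some sigma factor transcripts were lower as well. Synpcc7942_1849 stood at 0.0742 ± 0.00237 against 0.391 ± 0.0858 at 2 and 3 h, and at 0.318 ± 0.0155 against 1.44 ± 0.17 at 6 to 12 h (late difference -1.89 ± 0.09, adjusted p = 7.15e-18). Synpcc7942_1784 was lower by -1.26 ± 0.19 early and -1.49 ± 0.15 late. Synpcc7942_0569 was lower early (-1.24 ± 0.24), with 0.048 ± 0.19 late. Of the 6 factors other than the deleted one, 3 were lower early and 2 late, none was higher, and the list-alone counts were the same (limma camera, adjusted p = 0.0214 early and adjusted p = 0.372 late; adjusted p = 0.185 early with an estimated correlation and adjusted p = 0.0749 early with quantile normalization). The late counts became 3 higher and 2 lower with quantile normalization and 1 higher and 2 lower with centred libraries.

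Among the lowest transcripts late were the hypothetical protein Synpcc7942_0834 (0.0230 ± 0.00891 against 2.15 ± 0.178, log2 difference -3.89 ± 0.17), Synpcc7942_2185 (-2.68 ± 0.15), Synpcc7942_2388 (oxalate decarboxylase, -2.52 ± 0.14), Synpcc7942_2336 (-2.23 ± 0.28), the winged helix response regulator Synpcc7942_0556 (0.103 ± 0.00648 against 0.668 ± 0.0810, -1.91 ± 0.09) and Synpcc7942_0680 (C-5 sterol desaturase, -1.84 ± 0.13). Among higher transcripts, Synpcc7942_1426 stood at 2.27 ± 0.134 against 0.972 ± 0.0138 (1.15 ± 0.22). The tetrapyrrole synthesis enzymes Synpcc7942_0674 and Synpcc7942_0967 were higher by 1.06 ± 0.20 and 0.85 ± 0.22, while Synpcc7942_1838 was lower by -0.91 ± 0.08 (limma camera of this list, adjusted p = 0.393). Of the 4 ATP synthase subunits 3 were higher and none lower, 4 over the list alone, with Synpcc7942_0336 at 0.73 ± 0.19 and Synpcc7942_2315 at 0.63 ± 0.13 (limma camera, adjusted p = 0.00582, and adjusted p = 0.0544 with an estimated correlation).

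At 0 h 91 transcripts already differed, Synpcc7942_1426 at 11.9 ± 0.729 against 2.17 ± 0.766 and Synpcc7942_1784 at 0.0748 ± 0.0124 against 1.09 ± 0.438. Among the largest positive differences in response were those of Synpcc7942_2486 (3.37 ± 0.36) and Synpcc7942_0092 (3.29 ± 0.46), both hypothetical, and of the glycosyltransferase Synpcc7942_2026 (2.88 ± 0.21). It was smaller than in OX-D53E for Synpcc7942_0834 (-2.73 ± 0.33), Synpcc7942_2185 (-2.37 ± 0.30), Synpcc7942_0039 (-1.48 ± 0.28) and Synpcc7942_1849 (-1.42 ± 0.19).

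In all, 85 responses differed (36 higher, 49 lower; limma, adjusted 0.05), 181 mean levels (42 higher, 139 lower), 81 levels at 2 and 3 h (8 higher, 73 lower) and 142 at 6 to 12 h (32 higher, 110 lower). The median late difference of all transcripts was -0.14. In mean levels, of the dark carbon catabolism members 1 was higher and 7 lower (limma camera, adjusted p = 0.0107, and adjusted p = 0.0387 with an estimated correlation), all 4 ATP synthase subunits were higher (adjusted p = 0.00168 and adjusted p = 0.0376), and 2 of 3 carbon fixation transcripts were higher (adjusted p = 0.0417 and adjusted p = 0.0690; adjusted p = 0.0543 without the deleted factor). Of the 6 sigma factors other than the deleted one 4 were lower and the list did not pass (adjusted p = 0.0932), with 3 higher and 2 lower under quantile normalization and 1 higher and 3 lower with centred libraries. The counts over each list alone were the same. The balance of directions depended on scaling, and quantile normalization and centring largely set it themselves: higher and lower were 40 and 35, 104 and 92, 64 and 55, and 89 and 73 with quantile normalization, and 49 and 29, 95 and 101, 52 and 50, and 99 and 80 with centred libraries. The response count was 42 with pseudocount 0.01 and 163 without the 4 libraries rich in zeros, which also took the early count to 150.

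The rpoD5 deletion comparison, likewise within 1 sequencing season, gave a similar picture. At 2 and 3 h, 7 of the 8 dark carbon catabolism transcripts were lower than in OX-D53E, and at 6 to 12 h 6 were lower; none was higher (7 over the list alone at both times). Early, Synpcc7942_2602 stood at 0.202 ± 0.000871 against 0.870 ± 0.0649 (log2 difference -1.62 ± 0.17; limma, adjusted p = 2.72e-09), Synpcc7942_0245 differed by -1.54 ± 0.13 and Synpcc7942_0244 by -1.22 ± 0.12. Late, Synpcc7942_0039 differed by -1.27 ± 0.14, Synpcc7942_0245 by -0.94 ± 0.11 and Synpcc7942_2602 by -0.74 ± 0.14. The list passed camera early (adjusted p = 0.000434; adjusted p = 0.00652 with an estimated correlation) and late with the preset correlation (adjusted p = 0.0387; adjusted p = 0.116 with an estimated correlation). Late, quantile normalization left 3 members lower and 1 higher (adjusted p = 0.240), and centred libraries 5 lower and 1 higher.

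**Figure D2:**
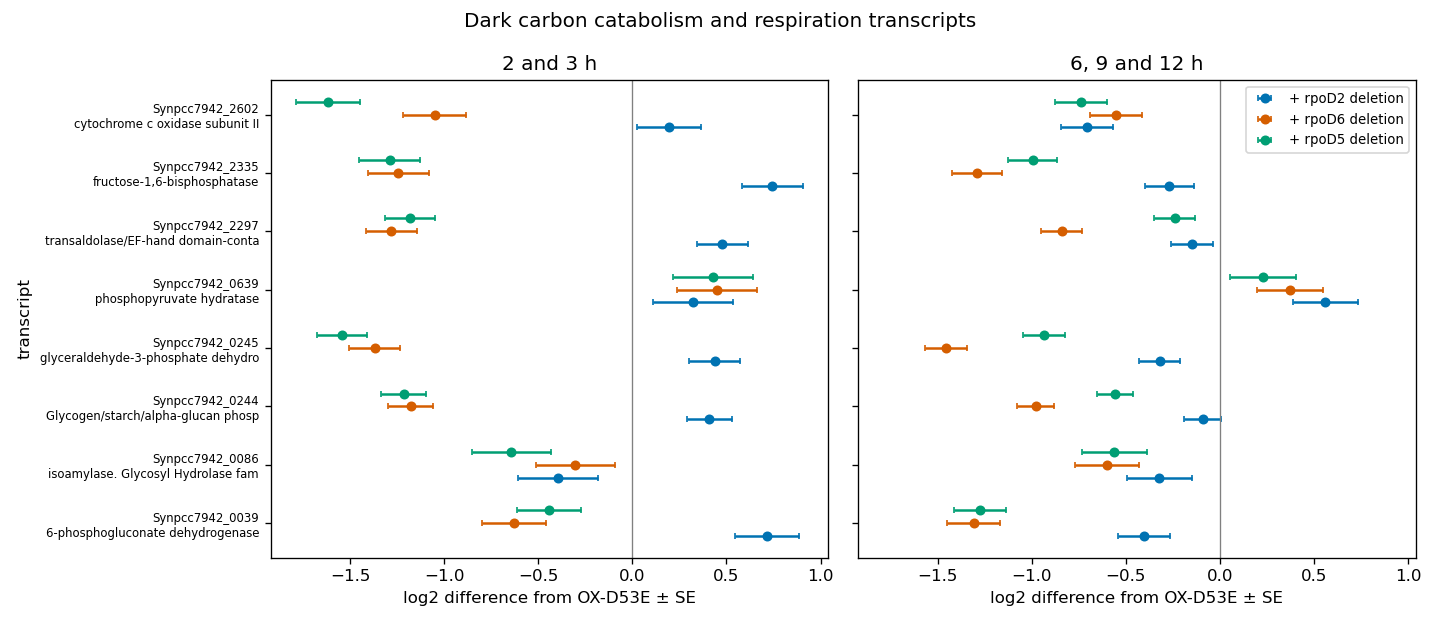
Log2 difference from OX-D53E of the 8 dark carbon catabolism and respiration transcripts in each deletion strain, with points at the fitted value and bars of 1 SE, for 2 and 3 h on the left and 6, 9 and 12 h on the right. In the rpoD6 and rpoD5 deletion strains 6 and 7 of the 8 were lower early and 7 and 6 late, and in the rpoD2 deletion strain 5 were higher early and 3 lower late; with quantile normalization the early counts of lower members were 5 and 5 for rpoD6 and rpoD5, the late ones 5 and 3, and 1 member was higher.

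Among sigma factors, Synpcc7942_1784 stood at 0.514 ± 0.0211 against 1.94 ± 0.0123 late (-1.72 ± 0.15, adjusted p = 2.85e-11) and was lower early by -1.16 ± 0.19. Synpcc7942_1557 changed sides, at 1.69 ± 0.0683 against 2.88 ± 0.388 early (-0.76 ± 0.20) and at 2.53 ± 0.120 against 1.41 ± 0.0961 late (0.86 ± 0.16, adjusted p = 4.39e-05); the early call was lost with quantile normalization. Synpcc7942_0569 was lower early (-1.59 ± 0.24) and Synpcc7942_1746 higher late (0.46 ± 0.09). Of the 6 factors other than the deleted one, 3 were lower early and none higher, 4 and 1 over the list alone (limma camera, adjusted p = 0.218), and 1 was lower and 2 higher late, the same over the list alone (adjusted p = 0.458). Early, quantile normalization gave 2 lower and 1 higher and centred libraries 3 lower and 1 higher.

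Other transcripts low at 6 to 12 h were Synpcc7942_2388 (0.248 ± 0.0124 against 1.53 ± 0.140, -2.26 ± 0.14), Synpcc7942_0834 (-2.12 ± 0.17), Synpcc7942_2336 (-1.79 ± 0.28) and the transhydrogenase subunit Synpcc7942_1612 (-1.55 ± 0.15). Synpcc7942_2082 (elongation factor G) and Synpcc7942_1108 (nucleoid protein Hbs) were lower early by -2.01 ± 0.15 and -1.99 ± 0.34. Higher late were Synpcc7942_2309 (0.74 ± 0.14), Synpcc7942_1426 (0.74 ± 0.22), Synpcc7942_0674 (0.70 ± 0.20) and Synpcc7942_0469 (phosphoglyceromutase, 0.64 ± 0.10). Of the ATP synthase subunits 2 were higher both early and late and none lower, over all transcripts and over the list alone (limma camera, adjusted p = 0.0254 early and adjusted p = 0.0868 late; early, adjusted p = 0.162 with an estimated correlation and adjusted p = 0.0561 with quantile normalization). At 0 h 84 transcripts differed, and Synpcc7942_1426 stood at 11.6 ± 1.44 against 2.17 ± 0.766. The response was larger than in OX-D53E for Synpcc7942_1557 (2.15 ± 0.32) and Synpcc7942_2026 (2.72 ± 0.21) and smaller for Synpcc7942_2388 (-1.80 ± 0.28) and Synpcc7942_1612 (-1.59 ± 0.30).

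In all, 73 responses differed (28 higher, 45 lower; limma, adjusted 0.05), 177 mean levels (48 higher, 129 lower), 103 levels at 2 and 3 h (15 higher, 88 lower) and 137 at 6 to 12 h (35 higher, 102 lower). The median late difference of all transcripts was -0.11. In mean levels 1 dark carbon catabolism member was higher and 7 were lower (limma camera, adjusted p = 0.00858, and adjusted p = 0.0662 with an estimated correlation), and 3 of 4 ATP synthase subunits were higher (adjusted p = 0.00858 and adjusted p = 0.0678), with the same counts over each list alone. Higher and lower were 34 and 29, 98 and 95, 71 and 59, and 77 and 67 with quantile normalization, and 35 and 22, 87 and 102, 56 and 53, and 74 and 76 with centred libraries. The response count was 36 with pseudocount 0.01, 138 without the 4 libraries rich in zeros and 32 and 31 without replicate 1 or 2 of the deletion strain; without replicate 1 the other counts were 110, 55 and 84, and the early count was 163 without the 4 libraries and 184 with array weights.

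Set directly against each other, the rpoD6 and rpoD5 deletion strains differed in 28 of 336 transcripts at 6 to 12 h (6 higher and 22 lower with rpoD6 deleted) and in 5 at 2 and 3 h. Besides the deleted factors, the transcripts lower with rpoD6 deleted included Synpcc7942_0834 (0.0230 ± 0.00891 against 0.481 ± 0.0190, log2 difference -1.77 ± 0.17; limma, adjusted p = 2.79e-10), Synpcc7942_2185 (-1.54 ± 0.15), Synpcc7942_0556 (-1.47 ± 0.09) and Synpcc7942_0680 (-1.42 ± 0.13). Synpcc7942_0331, an ATP synthase subunit, was higher (0.50 ± 0.12), as was the catalase-peroxidase Synpcc7942_1656 (0.35 ± 0.09). At 2 and 3 h the 5 were the deleted factors Synpcc7942_1557 and Synpcc7942_1849, Synpcc7942_1656 (0.59 ± 0.11), the hypothetical protein Synpcc7942_0687 (-0.71 ± 0.18) and Synpcc7942_0556 (-0.41 ± 0.10).

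The late differences from OX-D53E correlated across the 336 transcripts at r = 0.796 between the rpoD6 and rpoD5 deletions, and at 0.883 without Synpcc7942_1557, Synpcc7942_1849, Synpcc7942_1746 and Synpcc7942_1745. Transcripts are not independent replicates, and both differences use the same OX-D53E libraries. With a different OX-D53E replicate as the control of each strain, r was 0.739 and 0.747. In 100 simulations in which only the controls were shared, the mean r was 0.496. The covariance was 0.298, against 0.286 and 0.286 with separate controls and 0.0143 in the simulations. In both strains 92 transcripts were lower, the deleted Synpcc7942_1849 among them (33.4 if independent), and 24 were higher (3.33 if independent). Between rpoD6 and rpoD2 r was 0.328, or 0.303 and 0.270 with separate controls and 0.492 in the simulations, with a covariance of 0.117 against 0.0142 in the simulations and 38 transcripts lower in both (18.7 if independent) and 11 higher. Between rpoD5 and rpoD2 r was 0.421, or 0.392 and 0.350 with separate controls and 0.499 in the simulations, with a covariance of 0.134 against 0.0145 and 40 lower in both, again with Synpcc7942_1849 (17.3 if independent), and 12 higher.

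In the sigF2 deletion strain the question was which transcripts followed a cosine with a period of 24 h in constant light. The times from 24 to 44 h cover less than a full period. A passing fit therefore cannot tell a repeated cycle from a single rise and fall. Below, rhythmic means only that the fit passed. Of the 8 dark carbon catabolism members 6 passed the cosine test, 6 over the list alone, all with fitted peaks between 33 and 45 h. The library medians also changed over the day. With quantile normalization 8 passed, 7 of them with such peaks, and with centred libraries 7 and 6. Synpcc7942_2335 went from 0.0341 ± 0.00245 at 24 h to 0.751 ± 0.0563 at 36 h and 0.0388 ± 0.00605 at 44 h, a fitted peak-to-trough log2 range of 2.92 (limma, adjusted p = 6.14e-08). Synpcc7942_2297, Synpcc7942_0245, Synpcc7942_0039, Synpcc7942_2602 and Synpcc7942_0244 had ranges of 2.90, 2.61, 2.61, 2.17 and 1.99. Synpcc7942_0086 and Synpcc7942_0639 had fitted ranges of 0.14 and 0.19 (adjusted p = 0.503 and adjusted p = 0.704). Of the 7 sigma factors 3 passed, 3 over the list alone, against 4 with quantile normalization (5 over the list alone) and 6 with centred libraries. These 7 include the deleted Synpcc7942_1784, which was close to 0 in this strain and had no level to test. Synpcc7942_1849 went from 0.00873 ± 0.00348 at 24 h to 0.941 ± 0.126 at 36 h (range 3.55, fitted peak 34.1 h), Synpcc7942_1557 from 0.180 ± 0.00522 at 24 h to 2.48 ± 0.0490 at 32 h (range 3.08, peak 33.6 h), and Synpcc7942_1746 peaked at 22.2 h with a range of 1.15.

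The widest fitted range, 5.04, was that of the hypothetical protein Synpcc7942_0834 (peak 34.4 h, limma, adjusted p = 4.35e-06). Its level went from 0.0374 ± 0.010 at 24 h to 3.48 ± 0.140 at 36 h. Synpcc7942_2336, Synpcc7942_2267, Synpcc7942_0304 and Synpcc7942_1612 followed with ranges of 4.11, 3.87, 3.62 and 3.49 and peaks between 33.7 and 34.1 h. Before 33 h the widest fitted cycle was that of Synpcc7942_0556, at 0.516 ± 0.0122 at 32 h against 0.0198 ± 0.000872 at 24 h (range 2.10, peak 32.9 h). The response regulator Synpcc7942_0855, the purine synthesis enzyme Synpcc7942_0004 and the cellulose synthase Synpcc7942_0466 had ranges of 1.62, 1.21 and 1.05 with peaks at 21.3, 22.4 and 22.4 h.

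**Figure D3:**
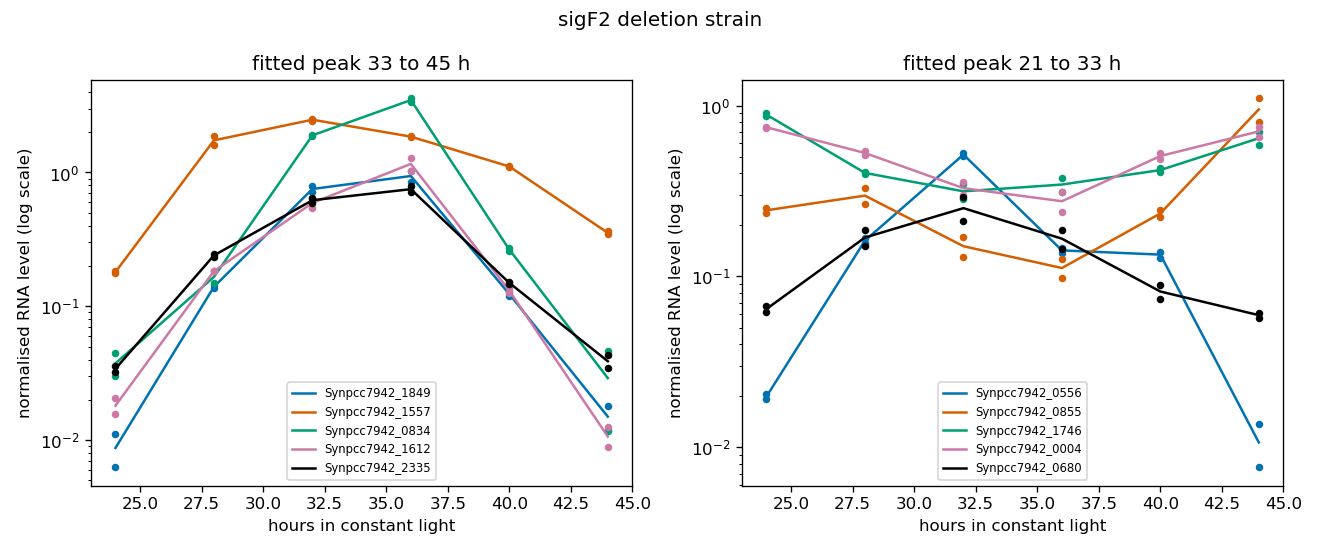
Normalised RNA level on a log axis against hours in constant light in the sigF2 deletion strain, for 5 transcripts with fitted peaks between 33 and 45 h on the left and 5 with fitted peaks between 21 and 33 h on the right; points are libraries and lines join the means of 2 replicates. Synpcc7942_0834 climbs from 0.0374 at 24 h to 3.48 at 36 h, while Synpcc7942_1746 is highest at 24 h, at 0.884.

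In all, 118 of 336 transcripts passed (limma F-test of the cosine terms, adjusted 0.05), 147 at an unadjusted p under 0.05, with a median peak-to-trough log2 range of 1.13. At least 118 calls came from 5 of 60 orders of the times, the real one included. Both replicates of a time moved together, so these orders bear on the shape over time. They cannot decide on chance, which is not excluded for this count. Fitted peaks lay between 21 and 27 h for 16, 27 and 33 h for 16, 33 and 39 h for 84, and 39 and 45 h for 2. The library medians rose and fell as well. They were 0.0846 at 24 h, 0.130 at 28 h, 0.157 at 32 h, 0.142 at 36 h, 0.114 at 40 h and 0.0957 at 44 h. The share of peaks between 33 and 45 h, 72.9% as deposited, was 47.3% of 148 calls with quantile normalization (81 of them shared) and 42.2% of 185 calls with centred libraries (79 shared); the calls of Synpcc7942_1556 and Synpcc7942_1960 were lost under both. Without replicate 1 or replicate 2 the counts were 35 and 36.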

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

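Among the tests in this part, those of sequencing season at 0 h were chosen only after the result was seen. The responses from 0 h to 6 to 12 h were set apart because they differed between strains by an interaction test in limma.

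In the rpoD2 deletion strain 181 responses differed from those of OX-D53E. Among its sigma factor transcripts the log2 difference in response was 1.04 for Synpcc7942_0569, -0.92 for Synpcc7942_0649, 2.56 for Synpcc7942_0672, 0.91 for Synpcc7942_1557, -3.58 for Synpcc7942_1784 and -2.24 for Synpcc7942_1849. In the rpoD6 deletion strain 85 responses differed, by 2.10 for Synpcc7942_0569, -1.59 for Synpcc7942_0672, 1.23 for Synpcc7942_1784, -1.42 for Synpcc7942_1849 and 1.06 for Synpcc7942_1746. In the rpoD5 deletion strain 73 responses differed, by 2.12 for Synpcc7942_0569, -1.24 for Synpcc7942_0672, 2.15 for Synpcc7942_1557 and 1.11 for Synpcc7942_1746. With a baseline of 0 and 0.5 h, the difference of Synpcc7942_1784 was -0.55 with rpoD6 deleted and -0.74 with rpoD5 deleted, and those of Synpcc7942_0649 and Synpcc7942_1557 with rpoD2 deleted were 0.028 and -0.044.

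Each response rests on its 0 h libraries, in which 178, 91 and 84 transcripts already differed from OX-D53E with rpoD2, rpoD6 and rpoD5 deleted. A single deviating OX-D53E library at 0 h is argued against as the whole cause. The median size of these differences against replicate 1 was 0.952, 0.780 and 0.747 of that against replicate 2. It was larger against replicate 2 in each strain, and that library has 24 transcripts at 0 against 1 in replicate 1. A part played by replicate 2 stays open. Season as the whole cause is argued against, since the lower of the counts in the strains sequenced in the same season as OX-D53E was 84. In the rpoD2 deletion strain the 178 differences cannot be told apart from season, because strain and season coincide. Cultures that were further into the response to light at 0 h stay open. For the called transcripts, the 0 h difference from OX-D53E replicate 2 was set against the 0 to 2 h change in replicate 1. The correlations were 0.379, 0.300 and 0.290. The deletions themselves may also act before induction, and this was not tested separately.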

How the results depend on the processing

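The alternatives with a pseudocount of 0.01, without the 4 libraries rich in zeros, with array weights, with centred libraries, with the sigma factor list without the deleted factor and with the 0.5 h library of OX-D53E replicate 2 left out were chosen after the data were seen. For 294 single values there were 5610 pairs of a value and an alternative setting. Of these pairs, 5270 kept direction and side of the threshold, 266 were no longer past it, 57 were newly past it and 17 changed sign. The share kept is high in part by design. Many values were picked as the largest differences, and some settings left out libraries of a strain outside the comparison. Counts within 1.5 times the reported ones are not listed. Leaving out libraries or strains leaves fewer samples. Beyond that, the cause of the changes below was not tested, except for the early counts without the 4 libraries rich in zeros.

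With pseudocount 0.01 the early and late counts were 35 and 44 with rpoD2 deleted, and the response counts 42 and 36 with rpoD6 and rpoD5 deleted. With only the strains compared, the early rpoD2 count was 43. Without the 4 libraries rich in zeros the early and late rpoD2 counts were 124 and 153, the rpoD6 response and early counts 163 and 150, and those of rpoD5 138 and 163. These counts rose although fewer samples were left. The 4 libraries are from 0.5 and 12 h, so differences at 2 and 3 h kept their size. The early counts moved through the variance, which was estimated over all strains and times. Array weights gave early counts of 154 for rpoD2 and 184 for rpoD5. Centred libraries gave 185 rhythmic transcripts. Of 49 list tests in the planned comparisons, 7 passed camera with the preset correlation, 5 when the factor deleted in a strain was left out, 3 with an estimated correlation, and 31 passed fry, which does not compare a list with other transcripts.

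Leaving out 1 replicate at a time gave 39 to 72 early calls for rpoD2. It gave 31 to 92 responses for rpoD5, with mean levels 110 to 210, early 55 to 115 and late 84 to 145. The rhythm count was 35 to 36. The lone library left at a time is assumed to vary like the others.

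In rpoD2 mean levels Synpcc7942_1849 was at -0.044 with pseudocount 1 and -0.017 with pseudocount 10. With pseudocount 10 Synpcc7942_1746 was at -0.039 in rpoD5 mean levels and Synpcc7942_1784 at -0.029 and -0.050 in the rpoD6 and rpoD5 responses. With quantile normalization Synpcc7942_0649 was at 0.36 and 0.24 in rpoD6 and rpoD5 mean levels, Synpcc7942_1557 at 0.39 in rpoD5, Synpcc7942_1746 at 0.33 in rpoD6 and Synpcc7942_1784 at -0.022 in rpoD2. With centred libraries Synpcc7942_1746 was at 0.018 in rpoD6 mean levels. Leaving out 1 replicate took Synpcc7942_1557 in rpoD5 mean levels from -0.21 to 0.18, the latter without OX-D53E replicate 1. With a baseline of 0 and 0.5 h Synpcc7942_1557 was at 0.69 in the OX-D53E response and -0.044 in the rpoD2 response, Synpcc7942_0649 at 0.028 in the rpoD2 response, and Synpcc7942_1784 at -0.55 and -0.74 in the rpoD6 and rpoD5 responses.

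A fixed replicate term gave response counts of 197 in OX-D53E and 188, 97 and 79 for rpoD2, rpoD6 and rpoD5, and 115 rhythmic transcripts. A random replicate term gave mean-level counts of 110, 163 and 147, early counts of 61, 82 and 98 and late counts of 81, 132 and 132 in the same order, with a correlation of 0.0748 within a series. Residuals of a series correlated at -0.485 to 0.686 between times. The rule set beforehand for pairing by replicate number asked for over 0.1 in every pair of times and was not met, though some libraries of a series deviated together. Over 0.1 were 14 of 21 pairs of times in OX-D53E, 15 in each of rpoD6 and rpoD5, 7 in rpoD2 and 3 of 15 in sigF2. The planned use of the first of several combined samples, and the alternatives for the ChIP-seq signal, were not run. With read depth unknown, small differences near 0 are limited to an unknown degree.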

Other observations

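In this part the tests of rhythm classes, of action through rpoD5 alone, of library scale as the cause of the correlation, of the construct at the deleted locus and of splits of whole replicate series were chosen only after the result was seen, as were all early and late differences. Transcripts that peaked in the subjective evening in the sigF2 deletion strain rose in OX-D53E, and were low without rpoD6 or rpoD5, more often than the others did. These libraries are independent of those of the OX-D53E background. Of 86 transcripts with fitted peaks between 33 and 45 h, 58 rose in OX-D53E (67.4% against 25.2% of the others; Fisher's exact test, adjusted p = 3.61e-11 over 28 tests). With rpoD6 deleted 65 of the 86 were lower late (75.6% against 18%, adjusted p = 2.00e-20), and with rpoD5 deleted 58 were (67.4% against 17.6%, adjusted p = 6.41e-16). With rpoD2 deleted 26 were higher early (30.2% against 8.4%, Fisher's exact test, adjusted p = 1.22e-05) and 24 were lower late (27.9% against 13.2%, adjusted p = 0.0067). The sigF2 and rpoD2 deletion strains were sequenced in the same season, and OX-D53E in a different one. Season and deletion therefore cannot be told apart in the overlaps with rpoD2 deleted. Of 32 transcripts with fitted peaks between 21 and 33 h, 8 were lower early with rpoD2 deleted (25% against 6.25%, adjusted p = 0.00481), the only passing test of that class. Of the same 32, 9 were higher early (28.1% against 12.5%, Fisher's exact test, adjusted p = 0.0596), so the calls ran in both directions. The 32 pool 16 transcripts with fitted peaks between 21 and 27 h and 16 with peaks between 27 and 33 h. These were not tested apart, so the calls in both directions may belong to different phases. With centred libraries, for which early differences were not examined, the class with fitted peaks between 33 and 45 h had 78 members. Of these, 56.4% rose in OX-D53E against 11.6% of the others. Lower late with rpoD6, rpoD5 and rpoD2 deleted were 55.1%, 52.6% and 16.7%, against 14.3%, 13.6% and 10.5%. Transcripts are not independent of one another, so these tests describe overlap only.

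Hydrogenase transcripts, which make the enzyme that exchanges electrons with hydrogen, included 5 of 7 that rose in OX-D53E and 4 of 7 lower late with rpoD6 and with rpoD5 deleted, and 4 of 7 were rhythmic, 5 over the list alone (limma camera, adjusted p = 0.158 in OX-D53E); quantile normalization left 3 that rose and 3 that were rhythmic, and centred libraries 3 that rose, 1 that fell and 2 that were rhythmic. Of 6 redox protection transcripts 2 rose and 4 fell in OX-D53E (limma camera, adjusted p = 0.110), and of 6 for cyclic di-GMP signalling 3 rose and 2 fell (adjusted p = 0.517), which became 3 that fell and none that rose with quantile normalization and with centred libraries. Of 6 transcription regulators 3 were lower late with rpoD6 deleted and 2 with rpoD5 deleted, and 3 were rhythmic; with quantile normalization these counts were 2, 1 and 4, and with centred libraries 2, 2 and 5. Late, limma camera of the regulators gave adjusted p = 0.234 and adjusted p = 0.611 with the deleted factor left out. Over all 336 transcripts as deposited, 121 rose in OX-D53E, 110 and 102 were lower late with rpoD6 and rpoD5 deleted, and 118 were rhythmic. The clock and output list held Synpcc7942_0644 and Synpcc7942_0677, both lower late with rpoD6 deleted and 1 of them with rpoD5 deleted, in the values as deposited. Other scalings of these differences were not examined for this pair. In the sigF2 deletion strain 1 of the pair was rhythmic as deposited, 0 with quantile normalization and 1 with centred libraries. In OX-D53E 1 of 2 NDH complex transcripts rose, 1 of 2 cytochrome b6f transcripts fell, 1 of 2 ribosomal protein transcripts rose and the other fell, and 1 of 2 pilus transcripts rose. The single chaperone and nitrogen assimilation transcripts rose as well. Neither of the 2 tRNA synthetases passed there, and both were rhythmic.

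The differences of the rpoD6 and rpoD5 deletions from OX-D53E at 6 to 12 h were alike. Shared OX-D53E libraries are argued against by the correlation of 0.739 with separate controls. Of 108 transcripts low without rpoD6, 20 (18.5%) were lower there than without rpoD5. This share is raised because the 108 were chosen as low in the same rpoD6 deletion libraries. Over all 336 transcripts, 22 were lower and 6 higher with rpoD6 deleted than with rpoD5 deleted, Synpcc7942_1557 among the lower. For the transcripts lower there, this argues against action of rpoD6 only through the level of rpoD5. With levels divided by the library median, the correlation was 0.722 and 0.731 with separate controls. A common factor shifts all log2 values of a library nearly alike, so it can alter a correlation across transcripts only through the pseudocount. These values therefore bear on the pseudocount and cannot decide on overall scale. For the number of transcripts lower in both, scale stays open, since 68.5% of them remained lower in both after centring. No test here separates the other explanations of the likeness.

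Synpcc7942_1745 was high at every time in the rpoD2 deletion strain, with time means from 9.92 to 14.2 and a highest-to-lowest ratio of 1.43, against 119 in OX-D53E. A level that hardly moves is consistent with transcription from the construct at the neighbouring deleted locus, a candidate explanation. A general rise of promoters with that time course on loss of the sigma factor is argued against by 19 transcripts. Their time course in OX-D53E correlated with that of Synpcc7942_1745 above 0.9, and their median late difference was 0.12 (range -1.26 to 0.64). They were chosen by time course alone, so they cannot speak on an effect limited to Synpcc7942_1745.

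Libraries of a replicate series deviated together in part, with residual correlations over 0.1 in 15 of 21 pairs of times in each of the rpoD6 and rpoD5 deletion strains, so single libraries may not be fully independent. Taken as units, the 2 series of a deletion strain and 2 of OX-D53E give 3 splits, too few for a share under 0.05. The other splits of whole series gave at most 34 calls, against 181, for rpoD6 mean levels and 0 for every other count of responses, mean levels, early levels and late levels. Exchanging single libraries within times takes them as independent. In 100 such splits the response, mean level and late counts for rpoD2 were 181, 143 and 88 against at most 175, 96 and 60 in the other splits. For rpoD6 mean levels and late levels they were 181 and 142 against at most 157 and 97, and for rpoD5 177 and 137 against at most 92 and 87. The response counts of 85 for rpoD6 and 73 for rpoD5 were reached in 2 and 4 of 100 splits, with highest others of 103 and 100, and in 4 and 3 of a second set of 100, with 117 and 82. For early counts there were 18 splits; the real counts were 74, 81 and 103 and the highest others 15, 31 and 24. For rhythm, 5 of 60 orders of the times gave at least the 118 calls observed, up to 151. Both replicates of a time moved together in these orders, so they bear on the shape over time. Whether the count arose by chance cannot be decided from them.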
